A study of Caenorhabditis elegans with 8 samples.

How the data were processed

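RNA was measured in whole young adult Caenorhabditis elegans of 2 genotypes, the wild-type strain N2 and the daf-16 mutant strain carrying the mgDf50 allele. Per the labels, worms grew on NGM plates (nematode growth medium) at 20 °C with a lawn of Escherichia coli that was either strain BW25113, the parent of a widely used collection of single-gene deletions, or a derivative of BW25113 lacking hns. The hns gene encodes H-NS, a DNA-binding protein that represses many bacterial genes. Genotype and food gave 4 groups with 2 libraries each. Total RNA was extracted with an RNeasy kit and libraries were made with the Lexogen SENSE mRNA kit, per the labels' protocols. Whether the libraries of a group came from separately grown worms is not stated, so the p-values measure the spread between these samples, which may be technical. The labels name no sequencing batch or date.

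The deposited values were FPKM (fragment counts scaled by transcript length and by library size), in 1 table for all 8 libraries. The authors used TopHat2 2.0.11, Cufflinks 2.2.1 and genome build ce10, per the submitters' processing notes; the annotation and the handling of strand are not given in the sources used here. The table had 41560 rows, of which 13398 were named as 21U small RNAs and 20764 were at 0 in every library. FPKM summed to between 2128460 and 2508481 per library, and the 10 most abundant genes held between 17.2% and 25.4% of a library's sum. No pair of libraries held identical values.

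The read counts behind the FPKM were not used here. Low FPKM values, up to 8.5 fragments, of coding genes with 1 transcript longer than 1000 nt were compared with whole multiples of the value of 1 fragment, using transcript lengths from a reference annotation. The best match put the libraries at 23500000 to 26600000 fragments. At that depth 53.5% to 56.8% of the low values lay within 0.15 of a whole fragment, against 30% by chance, so the depths are approximate and no count test was run. Lengths, gene classes and current names came from the WBcel235 reference, which is another build than ce10, so no coordinates are given. Of the 14564 genes tested, 14320 (98.3%) matched it by name.

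FPKM were transformed to log2(FPKM + 1), with a pseudocount of 1, and genes with at least 1 FPKM in at least 2 of the 8 libraries were kept. A fold change on this scale understates the change of genes with low FPKM. One linear model with a mean for each of the 4 groups was fitted to all 8 libraries in limma 3.58.1 (R 4.3.3), with a mean-variance trend (limma-trend). All groups shared 1 estimate of each gene's spread, with 4 residual degrees of freedom and 2.32 prior degrees of freedom. The 5 comparisons were hns against BW25113 food in wild type, the same in daf-16, daf-16 against wild type on BW25113 food, the same on hns food, and the interaction, defined as the food effect in wild type minus the food effect in daf-16. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison. An adjusted p under 0.05 counted as past the threshold. The food effects in the 2 genotypes have no library in common, and neither do the genotype effects on the 2 foods, although the estimate of spread is shared.

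Genes are named by a rule set before the data were examined. It takes daf-16 first. It then takes, per comparison, the 10 genes with the largest change in each direction among those past the threshold, with groups that do not overlap and at least 5 FPKM in the higher group. Members of fixed lists past the threshold are added, at most 4 per list and comparison. The genes sod-3, mtl-1, dod-3, hsp-16.2, lys-7, ftn-1, dod-24, hsp-6, hsp-60, hsp-4, gst-4, acdh-1 and fat-7 are given whether or not they passed. Some genes that the rule takes are not described in Results, and leaving them out was not part of the rule. Among them are F46A9.12, F46F11.11 and C16D9.9 (higher) and Y37E3.22 (lower) for the food effect in wild type. Others are acly-1, lower on hns food in daf-16, and C50C3.13 and K02C4.8, higher in daf-16 on both foods. A gene outside this rule is said to have been chosen after its values were seen. A gene listed at 0 in a group has no fold, because an exact 0 from Cufflinks can be a failed estimate.

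The 34 gene lists were written from general knowledge before the data were examined. They cover DAF-16-activated (class I) and DAF-16-repressed (class II) genes, the insulin-like signalling pathway, SKN-1 and xenobiotic detoxification, and infection-response and antimicrobial genes. They cover cytosolic heat shock, the mitochondrial and endoplasmic reticulum unfolded protein responses, lipid breakdown and fasting, fatty acid synthesis and desaturation, the propionate shunt and vitamin B12 response, iron handling, autophagy and lysosome, the mitochondrial respiratory chain, cytosolic ribosomal proteins and histones. Cell content is covered by vitellogenins, germline genes, yolk receptor, eggshell and oocyte genes, sperm genes, zygotic embryo genes, and markers of intestine, hypodermis and adult cuticle, muscle and neurons. Families were collagens, cytochromes P450, glutathione S-transferases, UDP-glucuronosyltransferases, C-type lectins, short-chain dehydrogenases, F-box A proteins, nuclear hormone receptors, and neuropeptide-like and FMRFamide-like genes. Each list with at least 3 members tested was tested with limma's camera at a preset correlation of 0.01 and adjusted over the 34 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, were run beside it. The p from fry depends on the order in which the groups enter the model, and all 24 orders were run. Members were counted past the threshold over all genes tested and adjusted over the list alone.

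The gene test was tested on 20 simulated data sets per comparison of 14260 genes, of which 200 were changed. The test recovered 55.2% of genes changed 2-fold and 80.2% of genes changed 4-fold for the food effect in wild type. The corresponding shares were 52.6% and 76.6% for the food effect in daf-16, 55.6% and 78% for the genotype effect on BW25113 food, 57.7% and 77.4% for the genotype effect on hns food, and 39.2% and 66.8% for the interaction. The mean number of false calls lay between 5.65 and 8.05. These sets had noise independent between genes. With correlated noise and no change the median number of genes called was 0 in every comparison, but 0 to 2 of 20 sets had calls. The mean was 298 and the maximum 5954 for the genotype effect on hns food, and the maximum was 23 for the food effect in wild type. A shared shift between libraries can thus give many false gene calls. In the sets with correlated noise all of it followed patterns shared by every gene, so their counts are not a false-call rate for the data. With no change simulated and correlated noise between genes, camera at the preset correlation called 8.05 to 9.2 of the 34 lists on average, and 43.2 of 170 over the 5 comparisons, against 44 in the data. Camera with an estimated correlation called 0. No changed list was simulated, so whether it could call one at this sample size is not known. A high p from it is therefore no evidence against a change. The list counts come from the same sets, so they are not a false-call rate either. They show that shared shifts alone can give many list calls at the preset correlation. Such calls are therefore weak evidence, and the p with an estimated correlation is given beside each.

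Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, quantile normalization, median ratio scaling, limma without the trend, limma-trend with robust estimation, a fit of only the libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the 697 tested genes listed at 0 in any library, leaving out genes with transcripts under 300 nt, the other orders of groups for fry, and leaving daf-16 out of the insulin-like signalling list. Near-identical gene copies, such as the major sperm protein genes, pud-3 and pud-4, and fipr-16 and F21C10.11, share fragments that Cufflinks could divide in different ways, so their values are uncertain. Overlapping and antisense genes are uncertain for the same reason where strand was not used.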

Results

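The transcriptomes of whole young adult C. elegans were measured as FPKM in 8 libraries, 2 for each combination of genotype (wild type N2 or the daf-16 mutant) and bacterial food (E. coli BW25113 or its hns deletion strain). DAF-16 is the FOXO transcription factor that insulin-like signalling holds in check. The series asks how hns-deficient bacteria act on DAF-16 and how this differs from reduced insulin-like signalling. Between 18137 and 18647 genes were above 0 in a library and between 13191 and 14099 reached 1 FPKM, at an implied depth of 23500000 to 26600000 fragments. Replicates correlated across genes with Pearson's r of 0.969 to 0.975 on the log2(FPKM + 1) scale, genes not being independent replicates. In a principal component analysis the first component held 24.7% of the variance and placed replicate 1 of wild type on hns food farthest out, at 53.5, with its partner at 20.1 and the other 6 libraries lower. In all 4 groups replicate 1 lay higher on this component than replicate 2, with a lower FPKM sum and more genes above 0.

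The transcript of daf-16 itself separated the genotypes. It stood at 77.1 and 77.4 FPKM in wild type on BW25113 food and at 75.6 and 69.9 FPKM on hns food, against 19.2 and 18.3 FPKM and 17.7 and 15.8 FPKM in the mutant. The mutant's level was 4.12-fold lower on BW25113 food (limma log2 fold change -1.99 ± 0.08 SE, adjusted p = 0.000516) and 4.34-fold lower on hns food (-2.05 ± 0.08, adjusted p = 0.00032). Food did not move daf-16 past the threshold in wild type (log2 fold change -0.09 ± 0.08, limma adjusted p = 0.57) or in the mutant (-0.15 ± 0.08, adjusted p = 0.823).

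In wild type, hns food lowered the heme transport genes hrg-1, hrg-3 and hrg-4 and the protease genes asp-10 and cpr-4, and raised F44G3.2, clec-258 and cth-1. The heme carrier gene hrg-3 fell from 494 ± 10.5 to 29.5 ± 0.471 FPKM (SD, n = 2), 16.7-fold, with a limma log2 fold change of -4.02 ± 0.08 (SE, adjusted p = 1.04e-05). The heme importer genes hrg-1 (5.08-fold) and hrg-4 (4.71-fold) fell with it, from 207 ± 24.2 to 40.8 ± 1.37 FPKM and from 188 ± 9.53 to 39.9 ± 5.88 FPKM (n = 2; limma adjusted p = 0.000806 and 0.00378). The aspartic protease gene asp-10, whose product is also described as a heme-homeostasis signal under the name HRG-7, fell 7.46-fold, from 680 ± 0.45 to 91.2 ± 5.77 FPKM (n = 2, limma adjusted p = 1.86e-05). The cathepsin B-like protease gene cpr-4 fell 5.28-fold and the omega-class glutathione transferase gene gsto-1 fell 6.1-fold (limma adjusted p = 0.00109 and 0.000558).

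Of the genes that rose on hns food in wild type, F44G3.2, clec-258, str-7 and H20E11.2 had means below 1 FPKM on BW25113 food. F44G3.2, an arginine kinase gene named argk-1 in the reference, rose from 0.249 ± 0.0565 to 93.2 ± 10.1 FPKM (SD, n = 2), a limma log2 fold change of 6.23 ± 0.12 (SE, adjusted p = 1.04e-05). The C-type lectin gene clec-258 rose from 0.186 ± 0.0903 to 48.5 ± 11.3 FPKM (n = 2, limma adjusted p = 0.000124). The cystathionine gamma-lyase gene cth-1, which makes cysteine from cystathionine, rose 11.7-fold, from 13.7 and 14.8 FPKM to 157 and 174 FPKM (limma adjusted p = 0.000163). The chemoreceptor-family gene str-7 rose from 0.0688 ± 0.0318 to 7.44 ± 0.0534 FPKM and H20E11.2 from 0.665 ± 0.0971 to 9.77 ± 3.7 FPKM (n = 2, limma adjusted p = 0.00333 and 0.0167).

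**Figure D1:**
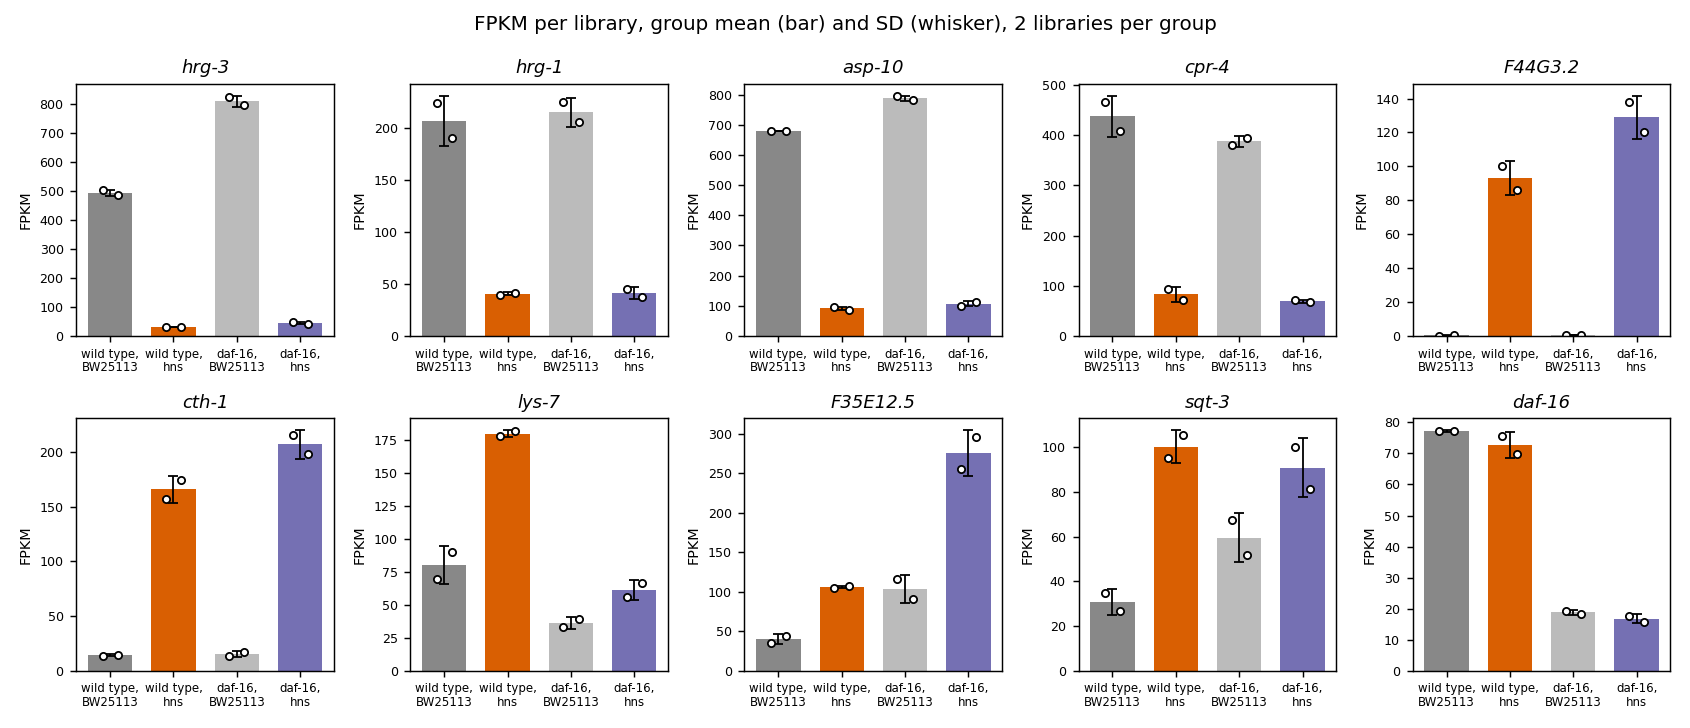
FPKM of 10 genes in each library (open circles), with the group mean (bar) and SD (whisker, n = 2); the vertical axes are linear and start at 0. Both hns-fed groups lie below 50 FPKM for hrg-3 and above 150 FPKM for cth-1, while daf-16 lies below 20 FPKM in every mutant library.

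Over the 5 comparisons 44 of 170 list tests passed with camera at the preset correlation. Simulations with no change and correlated noise gave a mean of 43.2 (12 to 62). All their noise followed patterns shared by every gene, so this is not a false-call rate for the data. Shared shifts alone can thus give as many passes, and a list's pass is not by itself evidence of a change. Among the fixed lists, the 51 tested infection-response and antimicrobial genes included 2 that rose over all genes tested, F35E12.5 (irg-5; 39.9 ± 6.44 to 106 ± 1.24 FPKM) and the lysozyme gene lys-7 (80 ± 14.4 to 180 ± 2.51 FPKM, n = 2; limma adjusted p = 0.024 and 0.0327). Adjusted over the list alone, 6 rose and 1 fell, and the median member stood at 0.21 on the log2 scale (camera adjusted p = 0.00725; adjusted p = 0.698 with an estimated correlation). Of 33 DAF-16-activated genes, lys-7 and the peroxisomal catalase gene ctl-2 (1.78-fold, limma adjusted p = 0.043) rose, 3 rose adjusted over the list alone and 0 fell. The list's median of 0.07 gave a camera adjusted p of 0.256, and the 12 DAF-16-repressed genes had a median of 0.05, a mean of -0.05 and a camera adjusted p of 0.725. Other genes often used as readouts of DAF-16 stayed short of the threshold, with log2 fold changes of -0.05 ± 0.19 for sod-3, 0.73 ± 0.69 for mtl-1, 0.43 ± 0.4 for dod-3, 0.72 ± 0.25 for hsp-16.2 and 0.11 ± 0.15 for dod-24 (SE; limma adjusted p of 0.255 to 0.897).

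In the list of propionate shunt and vitamin B12 response genes, 16 of 17 members lay below 0, with a median of -0.23 (camera adjusted p = 4.43e-06, or 0.698 with an estimated correlation). This list also holds genes outside the shunt, such as the methionine synthase gene metr-1. Over all genes tested acdh-1, the shunt's acyl-CoA dehydrogenase gene, fell 1.56-fold (1850 ± 52.1 to 1180 ± 69.1 FPKM) and Y38F1A.6 (hphd-1) fell 1.54-fold, both with n = 2 and a limma adjusted p of 0.032. Adjusted over the list alone, 8 fell. Of 9 iron-handling genes, 7 lay below 0 and hrg-1 and hrg-4 fell, in both adjustments (median -0.2, camera adjusted p = 0.00869; adjusted p = 0.658 with an estimated correlation; fry adjusted p = 0.00338). The ferritin gene ftn-1 gave -0.2 ± 0.33 (limma adjusted p = 0.749). In SKN-1 and xenobiotic detoxification, the methionine sulfoxide reductase gene msra-1 fell 3.3-fold and gst-38 rose 2.95-fold (limma adjusted p = 0.0198 and 0.024), as did ctl-2, in both adjustments. The list's median of 0.01 gave a camera adjusted p of 0.982 in the downward direction, and gst-4 gave -0.29 ± 0.1 (limma adjusted p = 0.26). The cytochrome P450 genes cyp-37B1 (4.13-fold) and cyp-35C1 (1.68-fold) rose (limma adjusted p = 0.0498 and 0.0397). Their list had a median of 0.17 (camera adjusted p = 0.0351; adjusted p = 0.698 with an estimated correlation), with 3 rising and 1 falling adjusted over the list alone. C-type lectins had a median of 0.15 (camera adjusted p = 0.0154; adjusted p = 0.658 with an estimated correlation; fry adjusted p = 0.0594). Over all genes clec-258 rose and clec-47 fell 5.87-fold (limma adjusted p = 0.0389), and 3 lectins rose and 1 fell adjusted over the list alone.

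Of 15 hypodermis and adult cuticle markers, 14 lay above 0 with a median of 0.76 (camera adjusted p = 1.58e-05; adjusted p = 0.658 with an estimated correlation; fry adjusted p = 0.0594). The collagen gene sqt-3 rose 3.25-fold, from 30.8 ± 5.69 to 100 ± 7.37 FPKM, and the hedgehog-related gene wrt-10 rose 3.51-fold, from 9.71 ± 1.99 to 34.1 ± 9.33 FPKM (SD, n = 2; limma adjusted p = 0.023 and 0.0482). Adjusted over the list alone, 6 markers rose. A set of 24 embryonic patterning genes, not one of the fixed lists, had a median of 0.66 in wild type and 0.23 in the mutant (22 and 19 above 0), with 0 past the limma threshold in wild type, and the fixed list of zygotic embryo genes had a median of 0.13 in wild type (camera adjusted p = 0.233). Further cuticle and epidermal genes past the threshold, chosen after their values were seen, were dpy-14, dpy-17, noah-1, noah-2, cut-2, cut-3 and mlt-11, with limma log2 fold changes of 1.39 to 1.76 and adjusted p of 0.0149 to 0.0466. The transcription factor genes pha-4, unc-120, ceh-43 and hbl-1, chosen in the same way, rose by 0.81 to 1.01 (limma adjusted p of 0.032 to 0.0464). The 102 collagens had a median of 0.22 (camera adjusted p = 0.00042; adjusted p = 0.783 with an estimated correlation), 0 passing over all genes and 14 rising adjusted over the list alone. Muscle markers (median 0.21), neuron markers (0.3), neuropeptide-like genes (0.23) and nuclear hormone receptors (0.15) also lay higher (camera adjusted p = 0.0161, 0.025, 0.0123 and 0.00347; adjusted p = 0.795 for each with an estimated correlation). Of these 4 lists only hlh-1, a muscle gene, rose adjusted over the list alone, and the receptors' direction turned with quantile normalization (camera adjusted p = 0.502). All 22 germline genes (median -0.15), all 20 yolk receptor, eggshell and oocyte genes (-0.19) and all 6 vitellogenins (-0.19) lay below 0 (camera adjusted p = 2.17e-05, 3.02e-05 and 0.00869; adjusted p = 0.698, 0.795 and 0.698 with an estimated correlation). By limma 0 of their members passed singly in either adjustment. The linker histone gene his-24 rose 2.22-fold (limma adjusted p = 0.0102) in a histone list with a median of 0. Without hns replicate 1 of wild type the camera adjusted p was 0.0553 for lectins, 0.156 for muscle markers, vitellogenins and cytochromes P450, 0.352 for nuclear hormone receptors, 0.822 for neuropeptide-like genes and 0.824 for neuron markers. Without BW25113 replicate 2 it was 0.132 for muscle markers and cytochromes P450, 0.251 for receptors, 0.426 for neuron markers and 0.764 for neuropeptide-like genes, without BW25113 replicate 1 it was 0.0538 for cytochromes P450, and without hns replicate 2 it was 0.803 for collagens.

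In all, 127 of 14564 genes passed in wild type, 94 higher and 33 lower on hns food, of which 14 were listed at 0 in a whole group. The excess of higher calls did not hold without a filter, with 31 higher and 29 lower, or without any 1 wild-type library, with 17 and 16 or 19 and 19 without BW25113 replicate 1 or 2 and 19 and 22 or 18 and 20 without hns replicate 1 or 2. The count was 488 with the replicate number as a block (414 higher, 74 lower), 204 with robust estimation and 42 with only the 4 libraries compared. It was 288 without genes listed at 0 in any library and 305 without transcripts under 300 nt, both chosen after seeing the data. The count fell to 84 and 83 without replicate 1 or 2 of daf-16 on hns food. The genes hrg-3, hrg-1, hrg-4, asp-10, gsto-1, F44G3.2, clec-258 and cth-1 passed in all 20 alternatives. Without any 1 of the 4 wild-type libraries lys-7, F35E12.5, acdh-1, Y38F1A.6, sqt-3, wrt-10, gst-38, ctl-2, clec-47, cyp-35C1 and cyp-37B1 no longer passed, their highest limma adjusted p over the alternatives lying between 0.112 and 0.252. Without either BW25113 library H20E11.2, his-24 and msra-1 no longer passed, nor did msra-1 without hns replicate 1 (highest 0.121, 0.0827 and 0.115).

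In daf-16 mutants, which test whether the response needs DAF-16, hns food moved the same leading genes. The transcript of hrg-3 fell 18.2-fold (808 ± 19.7 to 44.5 ± 5.08 FPKM), hrg-1 fell 5.2-fold, hrg-4 fell 4.62-fold and asp-10 fell 7.41-fold (SD, n = 2; limma adjusted p = 8.41e-06, 0.000645, 0.00317 and 2.64e-05). The protease genes cpr-4 and cpr-5 fell 5.58-fold and 7.91-fold, and gsto-1 fell 7.58-fold (limma adjusted p = 0.000805, 0.00369 and 0.000294). F44G3.2 rose from 0.648 ± 0.0723 to 129 ± 12.7 FPKM, clec-258 from 0.369 ± 0.19 to 52 ± 2.7 FPKM and cth-1 from 15.4 ± 2.89 to 207 ± 12.9 FPKM (n = 2; limma adjusted p = 8.41e-06, 0.000137 and 0.000137). The genes str-7, H20E11.2 and T22D1.17 rose too, T22D1.17 by 14-fold from 3.72 ± 1.38 to 52 ± 2.73 FPKM (n = 2; limma adjusted p = 0.00127, 0.014 and 0.0355).

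The immune, iron and B12-related lists pointed the same way in the mutant. F35E12.5 rose 2.67-fold (103 ± 17.8 to 276 ± 28.9 FPKM, n = 2, limma adjusted p = 0.0235), and 42 of 51 infection-response genes lay above 0 with a median of 0.29, 8 rising and 2 falling adjusted over the list alone (camera adjusted p = 1.77e-07; adjusted p = 0.503 with an estimated correlation). The lysozyme gene lys-7 did not pass (0.75 ± 0.15, limma adjusted p = 0.215). Iron-handling genes had a median of -0.16 (camera adjusted p = 0.00101; adjusted p = 0.503 with an estimated correlation; fry adjusted p = 0.00145). Both hrg-1 and hrg-4 fell over all genes, and ftn-2 with them adjusted over the list alone. The propionate shunt and vitamin B12 list had a median of -0.16 (camera adjusted p = 1.49e-06, or 0.681 with an estimated correlation), 3 members falling adjusted over the list alone. For acdh-1 the change of -0.6 ± 0.08 missed the threshold (limma adjusted p = 0.0507), and fat-7 gave 0.74 ± 0.12 (adjusted p = 0.114). DAF-16-activated genes lay slightly higher on hns food in the mutant (median 0.15, camera adjusted p = 0.0403; adjusted p = 0.768 with an estimated correlation), 0 passing over all genes and lys-7, ctl-2 and cyp-35B1 rising adjusted over the list alone. The camera adjusted p of this list was 0.0506 without hns replicate 2 of wild type, 0.288 without BW25113 replicate 2 of daf-16 and 0.961 without hns replicate 1 of daf-16. DAF-16-repressed genes had a median of -0.03 and a mean of 0.05 (camera adjusted p = 0.444, upward). The detoxification gene gst-38 rose 3.7-fold and msra-1 fell 3.29-fold (limma adjusted p = 0.0086 and 0.0204). Among C-type lectins clec-50 rose 1.77-fold and clec-47 fell 6.66-fold (limma adjusted p = 0.0491 and 0.0434), 9 rose and 2 fell adjusted over the list alone, and the camera adjusted p was 0.0646, or 0.0315 and 0.024 without BW25113 replicate 1 or hns replicate 2 of daf-16.

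Sperm genes had the lowest median of any list in the mutant, -0.74, with 37 of 41 below 0 (camera adjusted p = 1.31e-09; adjusted p = 0.768 with an estimated correlation). By limma 0 passed in either adjustment, and in wild type their median was -0.14 (camera adjusted p = 0.259), or -0.3 and -0.42 without BW25113 replicate 1 or hns replicate 2 of wild type (0.00292 and 0.00102). Many of these are near-identical major sperm protein genes whose fragments cannot be assigned with certainty. Cytochromes P450 (median 0.13), neuropeptide-like genes (0.15) and nuclear hormone receptors (0.07) lay higher and germline genes (-0.1) and respiratory chain genes (-0.06) lower (camera adjusted p = 0.00274, 0.00201, 0.0403, 0.000601 and 0.0218; adjusted p = 0.681, 0.768, 0.805, 0.768 and 0.805 with an estimated correlation). Adjusted over the list alone, 5 cytochromes P450 rose and 1 fell, and 0 members of the other 4 lists passed. The respiratory chain also pointed downward in wild type (camera adjusted p = 0.073). There it passed with the replicate block and without a filter (camera adjusted p = 0.017 and 0.0333, median -0.06 in both). Without replicate 2 of daf-16 on BW25113 food the respiratory chain's direction turned (camera adjusted p = 0.288) and cytochromes P450, neuropeptide-like genes, receptors and germline genes gave 0.244, 0.288, 0.718 and 0.234. Without hns replicate 1 of daf-16 neuropeptide-like genes, receptors and respiratory chain genes gave 0.621, 0.782 and 0.54, and without either BW25113 library of wild type receptors gave 0.0557 and 0.0526. Hypodermis and cuticle markers had a median of 0.26 (camera adjusted p = 0.287) and 0 passed; without hns replicate 2 of daf-16 the median was 0.16 (0.0296). In all, 59 genes passed in daf-16, 29 higher and 30 lower, 14 of them listed at 0 in a whole group. The calls were 31 higher and 17 lower without replicate 1 of daf-16 on BW25113 food. The count fell to 27 without replicate 2, and to 29 (11 higher, 18 lower) and 28 (9 higher, 19 lower) without replicate 1 or 2 on hns food. Without any 1 of the 4 daf-16 libraries T22D1.17, H20E11.2, msra-1, clec-47 and clec-50 no longer passed (highest limma adjusted p 0.315, 0.15, 0.172, 0.242 and 0.331), nor did gst-38 and F35E12.5 without BW25113 replicate 2 or either hns library of daf-16 (0.0969 and 0.189), F35E12.5 without either hns library of wild type, or hrg-4 without BW25113 replicate 2 of daf-16 (0.0511).

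The food responses of the 2 genotypes overlapped. Of the genes past the threshold, 15 rose in both (0.187 expected of independent lists), 21 fell in both (0.068 expected) and 1, the short non-coding RNA gene F35E12.13, moved in opposite directions. Across 14564 genes the food effects had a Spearman correlation of 0.532, genes not being independent replicates. The 27 genes that fell in wild type and were above 0 in every library all lay below 0 in the mutant, with medians of -1.32 in wild type and -1.44 in the mutant. Of 84 such genes that rose in wild type, 83 lay above 0 in the mutant, with medians of 1.38 and 0.464. Picked by the mutant instead, 21 genes that rose had medians of 1.79 in the mutant and 1.4 in wild type, and 23 that fell had -1.72 and -1.62. The side on which genes are picked is made larger by the picking. The number shared, 36, fell to 17 and 22 without BW25113 replicate 1 or 2 of wild type, to 23 without hns replicate 1 of wild type, to 17 without BW25113 replicate 2 of daf-16, and to 19 without either hns library of daf-16.

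**Figure D2:**
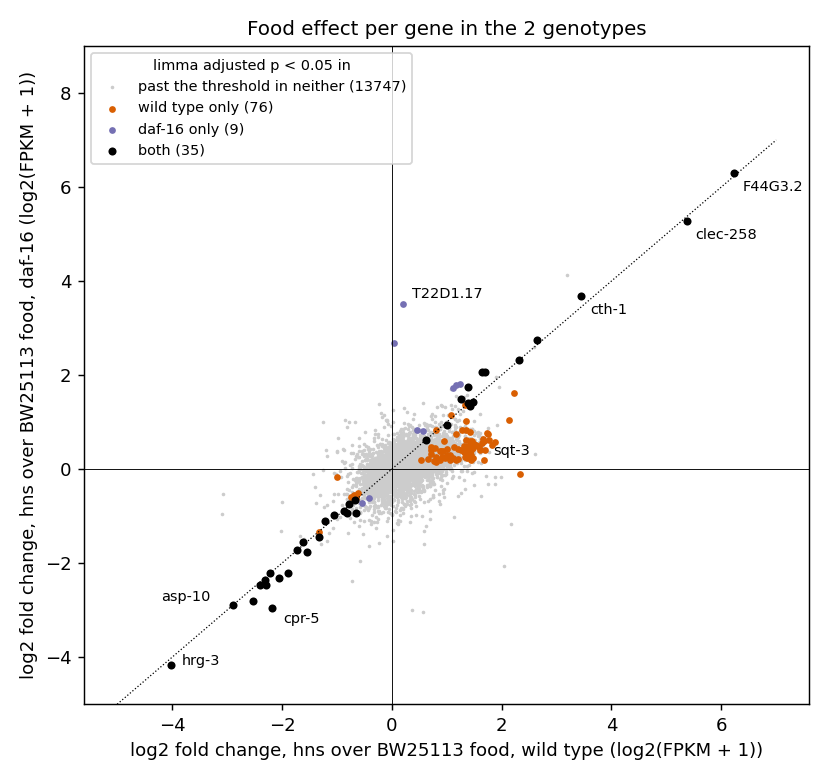
Log2 fold change on hns against BW25113 food in wild type (horizontal) and in daf-16 (vertical) for the 13867 tested genes above 0 in every library, on the log2(FPKM + 1) scale; the dotted line marks equal change. The 35 genes past the threshold in both genotypes lie near the line, whereas the 76 past it in wild type only include cuticle genes such as sqt-3 that lie below it.

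The interaction asked directly whether the food effect differed between genotypes. It called 14 genes, and each of them was listed at 0 in at least 1 whole group. The non-coding RNA gene F35E12.13 read 53.8 and 45.6 FPKM in wild type on BW25113 food and 44 and 46.1 FPKM in daf-16 on hns food, and was listed at 0 in the other 4 libraries (limma adjusted p = 5.44e-06). Y40H7A.309 was listed above 0 only in daf-16 on hns food (662 and 693 FPKM) and C16D9.13 only in wild type on hns food (370 and 360 FPKM; limma adjusted p = 5.44e-06 and 9.07e-06). Of the 14, 13 have annotated transcripts under 300 nt. With genes listed at 0 in any library left out, an alternative chosen after seeing the data, limma called 0 interactions, with 529 of 13867 genes at an unadjusted p under 0.05 and 693 expected by chance. Over all 14564 genes limma gave 539 at an unadjusted p under 0.05, but 959 with the replicate number as a block. The shortfall thus depended on how the replicates were modelled. The canonical genes gave interactions of 0.42 ± 0.21 for lys-7, -0.33 ± 0.27 for sod-3, 0.61 ± 0.97 for mtl-1, -0.04 ± 0.11 for acdh-1 and -0.47 ± 0.17 for fat-7 (SE, each with a limma adjusted p of 1). At this size the simulations recovered 39.2% of 2-fold interactions, so the lack of further calls does not show equal responses.

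Among lists, the interaction had medians above 0 for hypodermis and cuticle markers (0.93), sperm genes (0.51) and collagens (0.22), and below 0 for yolk receptor, eggshell and oocyte genes (-0.12) and vitellogenins (-0.13) (camera adjusted p = 5.1e-07, 0.000419, 0.00684, 0.000663 and 0.0222; adjusted p = 0.937 for each with an estimated correlation). By limma 0 of their members passed in either adjustment. Of these lists only the hypodermis and cuticle markers kept their call without each of the 8 libraries. Collagens turned direction without hns replicate 2 of wild type (camera adjusted p = 0.722) and gave 0.501 without hns replicate 2 of daf-16. Sperm genes gave 0.134, 0.543, 0.165 and 0.34 without BW25113 replicate 1 or hns replicate 2 of wild type or BW25113 replicate 2 or hns replicate 2 of daf-16. The oocyte list gave 0.179, 0.812 and 0.0652 without hns replicate 1 of wild type or BW25113 replicate 1 or hns replicate 2 of daf-16. Vitellogenins gave 0.0652 to 0.443 without any library other than hns replicate 2 of wild type or BW25113 replicate 2 of daf-16. DAF-16-activated genes gave a median difference of 0.04, 18 lying above and 15 below 0 (camera adjusted p = 0.895, downward). The count of interaction calls was 31 without a filter, 5 with a filter at 5 FPKM, 23 without the trend and 1 without transcripts under 300 nt, and 23 without either BW25113 library of wild type.

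**Figure D3:**
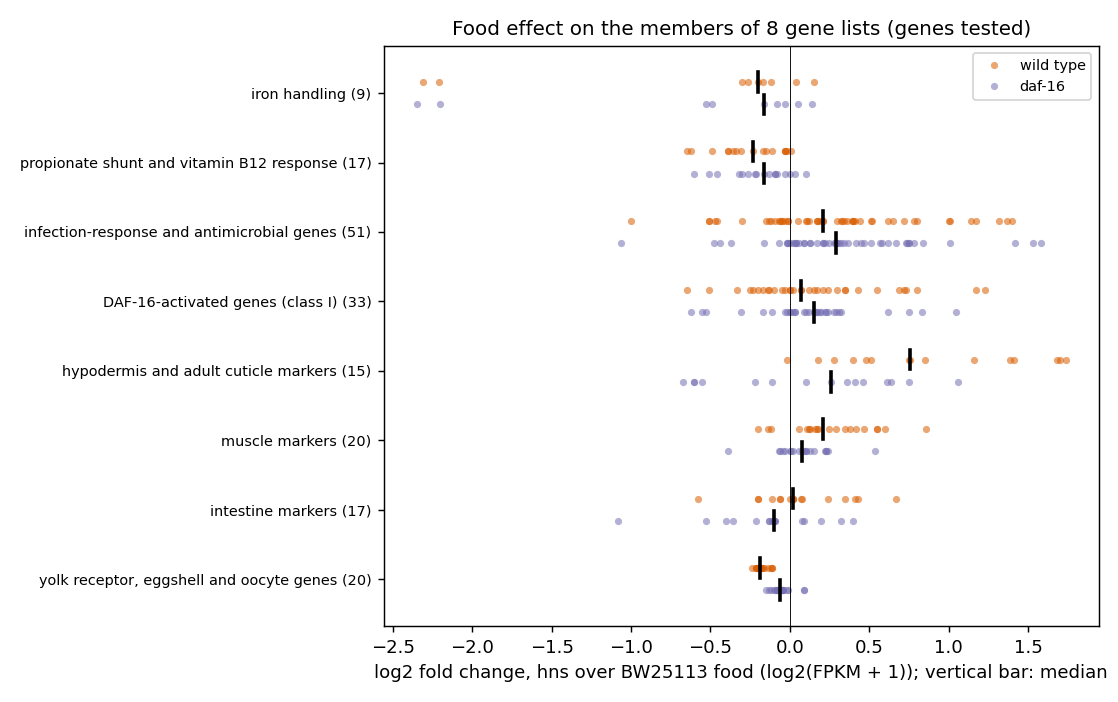
Log2 fold change on hns against BW25113 food of each tested member of 8 gene lists, on the log2(FPKM + 1) scale, in wild type and in daf-16; vertical bars mark medians and numbers in parentheses the genes tested. Hypodermis and cuticle markers have medians of 0.76 in wild type and 0.26 in daf-16, and the 2 lowest iron-handling points in each genotype are hrg-1 and hrg-4.

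Loss of daf-16 on BW25113 food lowered few genes past the threshold, apart from daf-16 itself. Y68A4A.13 fell 6.89-fold (30.7 ± 8.05 to 4.46 ± 0.836 FPKM), F15E6.3 3.45-fold (73.7 ± 15.9 to 21.3 ± 2.66 FPKM), pud-3 3.06-fold (758 ± 194 to 248 ± 12 FPKM) and the C-type lectin gene clec-222 2.09-fold (SD, n = 2; limma adjusted p = 0.0132, 0.0279, 0.0396 and 0.0162). F21C10.11 fell 4.59-fold (limma adjusted p = 0.0469) but has a near-identical copy, as does pud-3. Among genes that rose were cex-1, which encodes a calcium-binding calexcitin (2.85-fold, 15.5 ± 1.07 to 44.3 ± 7.71 FPKM), F35E12.5 (2.59-fold), F35E12.2 (3.55-fold), C44H4.10 (5.77-fold) and his-24 (2.05-fold), with n = 2 and limma adjusted p of 0.0396, 0.0448, 0.0469, 0.0448 and 0.0279.

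Of 33 DAF-16-activated genes, 27 lay below 0 in the mutant on BW25113 food, with a median of -0.33 (camera adjusted p = 1.48e-07; adjusted p = 0.467 with an estimated correlation). Over all genes 0 passed singly by limma, with 1328 of 14564 genes at an unadjusted p under 0.05, and btb-16, hil-1, lys-7, sip-1, sod-3 and spp-1 fell adjusted over the list alone. Among canonical members, mtl-1 read 37.4 ± 9.55 against 6.35 ± 3.1 FPKM (log2 fold change -2.43 ± 0.69), sod-3 3.99 ± 0.602 against 1.79 ± 0.393 FPKM (-0.84 ± 0.19) and lys-7 80 ± 14.4 against 36.1 ± 4.43 FPKM (-1.12 ± 0.15; SD for FPKM, n = 2; limma adjusted p = 0.328, 0.225 and 0.0755). The 12 DAF-16-repressed genes had a median of 0.23 (camera adjusted p = 0.0921, or 0.0375 with the replicate block and 0.0336 without BW25113 replicate 2 of daf-16). Insulin-like signalling genes had a median of -0.11 (camera adjusted p = 0.000718; adjusted p = 0.467 with an estimated correlation), a list that holds daf-16 itself, its only member to pass over all genes. With daf-16 left out, chosen after the result was seen, the other 24 had a median of -0.1 (camera adjusted p = 0.00991; adjusted p = 0.617 with an estimated correlation), 0 passing over all genes. Lipid breakdown (median -0.08), propionate shunt (-0.09) and neuron lists (-0.15) lay lower (camera adjusted p = 0.0103, 0.00871 and 0.0204; adjusted p = 0.467, 0.727 and 0.829 with an estimated correlation), 0 members passing in either adjustment. Without BW25113 replicate 2 of daf-16 the camera adjusted p was 0.0701 for lipid breakdown and 0.347 for neurons, without BW25113 replicate 1 of wild type it was 0.652 for neurons, and without BW25113 replicate 2 of wild type or replicate 1 of daf-16 it was 0.0604 and 0.222 for the propionate shunt.

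Some tissue-content lists also passed between genotypes on this food with camera at the preset correlation, which is weak evidence of a difference. Sperm genes (median 0.62), hypodermis and cuticle markers (0.64), collagens (0.31) and muscle markers (0.26) lay higher in daf-16, and yolk receptor, eggshell and oocyte genes (-0.2) lower (camera adjusted p = 8.08e-06, 6.95e-05, 0.000136, 0.0227 and 1.17e-06; adjusted p = 0.748, 0.617, 0.727, 0.748 and 0.727 with an estimated correlation). By limma 0 members passed over all genes; adjusted over the list alone, sqt-3 and wrt-10 rose and 0 members of the other 4 lists passed. Muscle markers gave camera adjusted p of 0.355 and 0.442 without BW25113 replicate 2 of wild type or of daf-16. In all, 38 genes passed, 22 higher and 16 lower, 15 of them listed at 0 in a whole group. Quantile normalization gave 11 higher and 13 lower (45.8% higher against 57.9%). The count was 23 with a pseudocount of 5, 21 with median ratio scaling, 22 without the trend and 22 with only the libraries compared. The count was 12 (4 higher, 8 lower) and 23 without replicate 1 or 2 of daf-16 on BW25113 food, 20 and 19 without replicate 1 or 2 of wild type on BW25113 food and 24 without hns replicate 2 of wild type. Without any 1 of the 4 BW25113 libraries cex-1, F35E12.5, F35E12.2, C44H4.10, F21C10.11 and clec-222 no longer passed (highest limma adjusted p over the alternatives 0.22, 0.271, 0.25, 0.277, 0.248 and 0.16). Nor did pud-3 and F15E6.3 without either BW25113 library of daf-16 or without BW25113 replicate 2 or 1 of wild type (0.248 and 0.232), his-24 without either BW25113 library of wild type or replicate 1 of daf-16 (0.17), or Y68A4A.13 without replicate 1 of daf-16 (0.178).

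On hns food, loss of daf-16 lowered the lysozyme gene lys-7 2.94-fold, from 180 ± 2.51 to 61.2 ± 7.25 FPKM, and clec-222 2.38-fold, from 68.7 ± 5.17 to 28.9 ± 0.772 FPKM (SD, n = 2; limma adjusted p = 0.0225 and 0.00715). Y54G2A.36 (1.84-fold) and K11D12.13 (1.76-fold) fell too (limma adjusted p = 0.0109 and 0.0189). F35E12.5 rose 2.6-fold (106 ± 1.24 to 276 ± 28.9 FPKM), the lysozyme gene lys-1 1.46-fold (369 ± 25.2 to 538 ± 5.64 FPKM) and the small nucleolar RNA gene ZK185.9 4.47-fold (n = 2; limma adjusted p = 0.0424, 0.0466 and 0.0218). Of 33 DAF-16-activated genes, 26 lay below 0 with a median of -0.32 (camera adjusted p = 1.02e-06; adjusted p = 0.469 with an estimated correlation). Over all genes lys-7 fell, and hsp-12.6, lys-7, mtl-1, pck-1, sip-1, sodh-1 and spp-1 fell adjusted over the list alone. The metallothionein gene mtl-1 read 120 and 31.3 FPKM in wild type and 10.2 and 4.2 FPKM in daf-16 (limma log2 fold change -3.04 ± 0.69, adjusted p = 0.287), and sod-3 gave -0.51 ± 0.19 (adjusted p = 0.589). DAF-16-repressed genes lay higher, 11 of 12 above 0 with a median of 0.33 (camera adjusted p = 0.000554; adjusted p = 0.404 with an estimated correlation), and dod-19 and clec-186 rose adjusted over the list alone.

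Infection-response genes (median 0.21) also lay higher and insulin-like signalling genes (-0.06) and neuron markers (-0.32) lower in daf-16 on hns food (camera adjusted p = 0.00136, 0.00219 and 0.00165; adjusted p = 0.766, 0.561 and 0.989 with an estimated correlation). Without daf-16 in it, the insulin-like signalling list gave a camera adjusted p of 0.0317 (adjusted p = 0.781 with an estimated correlation). On BW25113 food the infection-response list also pointed upward, short of the threshold (camera adjusted p = 0.0535, or 0.0299 with quantile normalization). On hns food F35E12.5 and lys-1 rose and lys-7 fell over all genes among infection-response genes, 8 rising and 3 falling adjusted over the list alone. Without hns replicate 1 of daf-16 the camera adjusted p of that list was 0.151, and that of neuron markers was 0.575 without hns replicate 1 of wild type and 0.275 without hns replicate 2 of daf-16. Hypodermis and cuticle markers had a median of -0.18 and sperm genes of 0.1 (camera adjusted p = 0.183 and 0.769). Without hns replicate 1 of daf-16 the hypodermis median was -0.41 (camera adjusted p = 0.00636). The sperm median was -0.18 and -0.13 without hns replicate 1 of wild type or of daf-16 (camera adjusted p = 0.0122 and 0.0276), and 0.35 and 0.36 without hns replicate 2 of wild type or of daf-16 (0.00391 and 0.0043). In all, 34 genes passed, 24 higher and 10 lower, 16 of them listed at 0 in a whole group, and 22 passed without genes listed at 0 in any library (chosen after seeing the data). The count was 21 and 13 without hns replicate 1 or 2 of wild type and 10 without either hns library of daf-16, where the balance turned to 4 higher and 6 lower without replicate 1 and 3 higher and 7 lower without replicate 2. Without any 1 of the 4 hns libraries lys-7, Y54G2A.36, K11D12.13, F35E12.5, lys-1 and ZK185.9 no longer passed (highest limma adjusted p over the alternatives 0.189, 0.122, 0.189, 0.264, 0.265 and 0.195), nor did clec-222 without either hns library of daf-16 (0.0977).

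The genotype effects on the 2 foods shared 8 genes that rose (0.0363 expected of independent lists) and 5 that fell (0.011 expected), with 1 in opposite directions and a Spearman correlation of 0.348 across genes. Those that fell were daf-16, clec-222, Y54G2A.36, K11D12.13 and K06A4.15, the last listed at 0 in the mutant. Those that rose included cex-1, F35E12.5, F35E12.2 and, chosen after its values were seen, the phosphatase-family gene scpl-1, which went from 75.7 ± 0.504 to 132 ± 0.255 FPKM on BW25113 food and from 72.3 ± 2.08 to 126 ± 3.47 FPKM on hns food (SD, n = 2; limma adjusted p = 0.00538 and 0.00541).

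**Figure D4:**
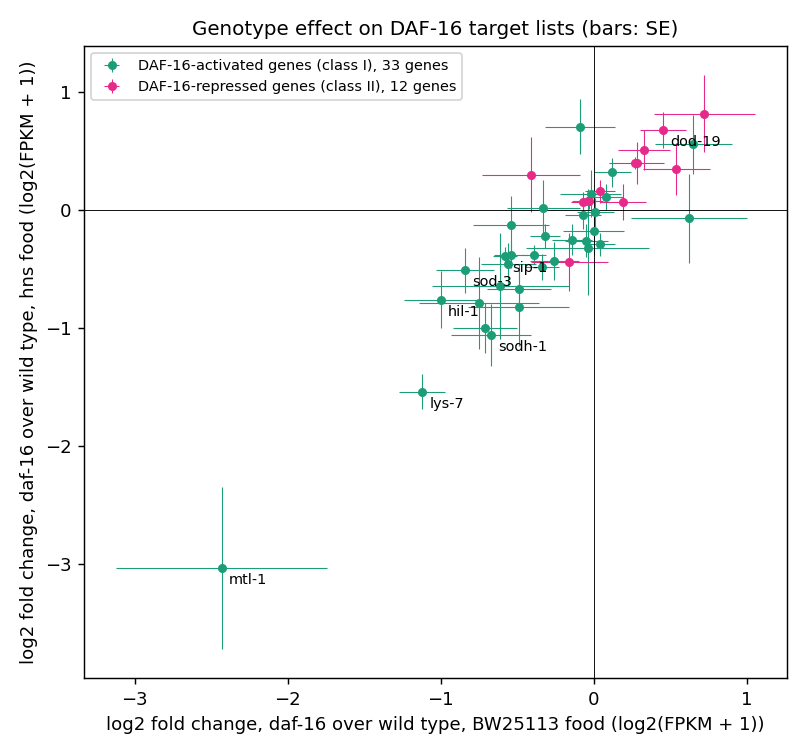
Log2 fold change in daf-16 against wild type on BW25113 food (horizontal) and on hns food (vertical) for 33 DAF-16-activated and 12 DAF-16-repressed genes, on the log2(FPKM + 1) scale; bars show SE. The activated genes have medians of -0.33 and -0.32 on the 2 foods, and mtl-1 and lys-7 lie lowest on hns food.

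The remaining 14 lists passed in 0 of the 5 comparisons, although 8 of them passed in at least 1 under some alternative. The lowest camera adjusted p of each was 0.0733 for intestine markers, 0.0749 for cytosolic ribosomal proteins, 0.0752 for the mitochondrial unfolded protein response, 0.0886 for cytosolic heat shock, 0.0899 for glutathione S-transferases, 0.183 for SKN-1 and xenobiotic detoxification, F-box A proteins and fatty acid synthesis and desaturation, 0.232 for zygotic embryo genes, 0.255 for UDP-glucuronosyltransferases, 0.289 for autophagy and lysosome, 0.306 for the endoplasmic reticulum unfolded protein response, 0.32 for short-chain dehydrogenases and 0.655 for histones. The chaperone genes hsp-6, hsp-60 and hsp-4 gave limma log2 fold changes between -0.18 and 0 in the 5 comparisons, with adjusted p of 0.287 or more. The ribosomal protein list depended on single libraries of several groups. Without BW25113 replicate 1 of daf-16 its medians were -0.15 for the food effect in daf-16, 0.12 for the genotype effect on BW25113 food and 0.14 for the interaction. Without BW25113 replicate 2 of daf-16 the genotype effect on BW25113 food turned to -0.07. Without hns replicate 1 of wild type the medians were -0.08 for the genotype effect on hns food and 0.11 for the interaction. Without hns replicate 2 of wild type the median was -0.07 for the food effect in wild type. For the food effect in daf-16 the replicate block gave -0.05 (camera adjusted p = 0.0258), and quantile normalization turned it to 0.03 (camera adjusted p = 0.0417). With quantile normalization F-box A proteins had a median of -0.19 and the endoplasmic reticulum unfolded protein response of 0.07 for the food effect in wild type (camera adjusted p = 0.000496 and 0.0148). The latter also passed without BW25113 replicate 1 of daf-16 for the genotype effect on that food (0.0042) and without replicate 2 for the food effect in daf-16 (0.00304). Intestine markers passed for the interaction with quantile normalization (camera adjusted p = 0.0153) and without hns replicate 2 of wild type (0.0131) or BW25113 replicate 1 of daf-16 (0.0263).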

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

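The tests of technical and biological explanations in this part were chosen only after the result was seen, except the test of the median of embryonic patterning genes, whose outcome was predicted first; the interaction tests themselves were fixed before the data were examined.

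The interaction between food and genotype passed for 14 genes, each listed at 0 in at least 1 group. Of these, 92.9% (13 of 14) have annotated transcripts of 91 to 216 nt, against 5.19% under 300 nt among 14320 tested genes, and the remaining gene, Y44A6D.1, has 1706 nt; an all-or-none estimate for short transcripts may therefore lie behind most of these calls. A difference in depth is argued against, because the highest group mean of the implied depth was 1.05 times the lowest. A food response that depends on daf-16 stays open: among 13867 genes above 0 in every library limma called 0 interactions, with 529 at an unadjusted p under 0.05, while the simulations recovered 39.2% of 2-fold and 66.8% of 4-fold interactions. A short RNA that is switched on in 1 group and an estimate that failed in the others cannot be told apart for these genes, because FPKM holds no record of failed estimates.

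The lowest p of these calls were those of F35E12.13, Y40H7A.309 and C16D9.13 (limma adjusted p = 5.44e-06, 5.44e-06 and 9.07e-06). No size is given for the interactions, because the pseudocount sets it for a gene listed at 0. With a filter at 5 FPKM these 3, T23D8.11 and linc-28 passed, and the other 9 did not. T23D8.11 read 220, 182, 0 and 0 FPKM in wild type and 393, 590, 522 and 546 FPKM in daf-16, on BW25113 and then hns food (limma adjusted p = 0.000175). The following were above 0 in a single group. In wild type on hns food linc-28 read 54 and 52.6 FPKM (limma adjusted p = 0.000175). In wild type on BW25113 food C17B7.14 read 15.8 and 13.8 FPKM and T09A12.8 read 7.26 and 6.42 FPKM (limma adjusted p = 0.00292 and 0.016). In daf-16 on BW25113 food rrn-4.3 read 35 and 35.3 FPKM and M162.15 read 5.97 FPKM in both libraries (limma adjusted p = 0.000348 and 0.018). F10D7.9 and Y44A6D.1 were above 0 in the same group (limma adjusted p = 0.00179 and 0.00298, or 0.706 and 0.998 with a filter at 5 FPKM). In daf-16 on hns food F42G8.16 read 8.23 and 8.73 FPKM, Y95B8A.16 read 5.48 and 5.84 FPKM and F55B12.14, chosen after its values were seen, read 4.17 and 4.45 FPKM (limma adjusted p = 0.00798, 0.0207 and 0.0464).

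Hypodermis and adult cuticle markers lay higher on hns food in wild type, with a median interaction of 0.93 (camera adjusted p = 5.1e-07, or 0.937 with an estimated correlation). The fry adjusted p of this interaction was 0.628 to 0.993 over the orders of groups. A single wild-type library as the only source of the food shift in wild type is argued against. The median of 0.76 was 0.81, 0.49, 0.52 and 1.42 without BW25113 replicate 1, BW25113 replicate 2, hns replicate 1 and hns replicate 2 of wild type. The size of the shift thus depended on the library left out. The daf-16 libraries, which enter the interaction, were not left out in this test. A lower germline share that raised all body tissues alike stays open. The 58 muscle, neuron and intestine markers had a median of 0.23, below that of the 15 hypodermis markers. The difference of list means was 0.661 with 1 value per library (95% interval 0.327 to 0.994 with 4 residual degrees of freedom), and 0.63 to 0.69 without any 1 library. The hypodermis list was flagged for its shift in these same libraries. The interval does not allow for that picking and cannot decide. More embryos inside the animals is a candidate explanation: 24 embryonic patterning genes, 1 of which is in another list, had a median of 0.66 in wild type, with 22 above 0 and 0 past the limma threshold (mean above that of all tested genes by 0.493 with 1 value per library, 95% interval 0.406 to 0.581; median 0.61 to 0.68 without any 1 of the 4 wild-type libraries). Their most abundant members pal-1 (366 ± 16.8 to 325 ± 39.2 FPKM, SD, n = 2) and tbx-9 (36.3 ± 0.811 to 31.1 ± 1.05 FPKM) were not higher. RNA of whole animals does not separate embryos from the germline, so these genes cannot decide. The fixed list of 14 zygotic embryo genes had a median of only 0.13 (camera adjusted p = 0.233). Hypodermis markers and patterning genes were also lower in wild type than in daf-16 on BW25113 food (median genotype effects 0.64 and 0.35). A difference in age or egg content of wild type on BW25113 food therefore stays open.

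For the other lists the interaction had medians of 0.51 for sperm genes (34 of 41 above 0), -0.12 for yolk receptor, eggshell and oocyte genes (20 of 20 below 0), 0.22 for collagens (71 of 102 above 0) and -0.13 for vitellogenins (6 of 6 below 0). Their camera adjusted p were 0.000419, 0.000663, 0.00684 and 0.0222, and the adjusted p was 0.937 for each with an estimated correlation.

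The heme transport genes hrg-1, hrg-2, hrg-3, hrg-4 and mrp-5, with asp-10, were lower on hns food in both genotypes. Scaling between libraries is argued against, because under quantile normalization and median ratio scaling the 6 genes kept log2 fold changes of -4.15 to -0.96 in both genotypes. A general fall of lysosomal genes stays open. The 25 autophagy and lysosome genes had medians of -0.03 in wild type and 0.03 in daf-16. Most of them are autophagy genes, so a median over them cannot decide for lysosomal genes. An altered supply of heme from hns-deficient bacteria may lower these genes, but the heme-responsive genes hrg-9 and hrg-10 had a mean log2 fold change of -0.19 over both genotypes (-0.04 and -0.26 for hrg-9, -0.33 and -0.13 for hrg-10), too small to decide. The heme content of the bacteria and of the animals was not measured here.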

How the results depend on the processing

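The alternatives that left out genes listed at 0 or short transcripts, the other orders of groups for fry and daf-16 left out of its list were chosen only after the result was seen; the others were fixed before. Among the named genes and comparisons, 2943 of 3434 values kept their side of the threshold, 49 of them changing sign short of it, 478 no longer passed, 13 passed anew and 0 changed sign with a pass on either side; among list tests 2128 of 2380 kept their side, 144 no longer passed, 99 passed anew and 9 reversed. In 199 cases a named gene was not tested under an alternative. The cause was not tested except where stated.

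The food effect in wild type (127 genes) gave 60 without a filter, where 20796 genes were tested, 204 with robust estimation, 42 with only the libraries compared, 488 with the replicate number as a block, 288 without genes listed at 0 and 305 without transcripts under 300 nt, and 33 to 94 leaving out 1 library. The labels do not say that replicate numbers pair libraries between groups, but a shift shared by replicate number is not excluded: deviations of replicate 1 from its group mean correlated between groups at 0.0219 to 0.161, each above 0. The block gave 62, 40, 36 and 14 calls for the other comparisons. With it 51 list tests passed with camera, against 44. Among those that passed anew were neuron markers and collagens, both upward, for the food effect in daf-16 (camera adjusted p = 0.00302 and 0.00251, against 0.0635 and 0.0708). The food effect in daf-16 (59) gave 27 to 64 leaving out 1 library. The genotype effect on BW25113 food (38) gave 23 with a pseudocount of 5, 24 with quantile normalization, 21 with median ratio scaling, 22 without the trend, 22 with only the libraries compared, and 12 to 29 leaving out 1 library. The genotype effect on hns food (34) gave 22 without genes listed at 0 and 10 to 37 leaving out 1 library. The interaction (14) gave 31 without a filter, 5 with a filter at 5 FPKM, 23 without the trend, 0 without genes listed at 0 (529 at an unadjusted p under 0.05 by limma), 1 without transcripts under 300 nt, and 11 to 23 leaving out 1 library; a fit of only the libraries compared is the same fit for it and was not run. Shared food calls (36) numbered 17 to 31 leaving out 1 library. A group left with 1 library is assumed to vary like the other groups.

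Of 170 list tests, 44 passed with camera (a mean of 43.2 with no change simulated), 44 with daf-16 left out of its list, 0 with an estimated correlation and 2 with fry. Over the 24 orders in which the groups can enter the model, 2 to 4 passed with fry: iron handling in both genotypes in every order, hypodermis markers (0.0329 to 0.0616) and C-type lectins (0.0329 to 0.0594) in 10 and 16 of them for the food effect in wild type. Of the 99 that passed anew, 19 did so without hns replicate 2 of wild type, 18 and 14 without BW25113 replicate 1 or 2 of daf-16. Among those not named above, camera adjusted p was 4.93e-06 for the oocyte list's food effect in daf-16 and 7.94e-07 for the muscle interaction without BW25113 replicate 1 of daf-16, and 0.000153 for muscle in daf-16 without replicate 2. Neuropeptide-like genes gave 0.000123 for the genotype effect on BW25113 food without BW25113 replicate 2 of wild type and 0.000718 on hns food without hns replicate 2 of wild type. Quantile normalization reversed nuclear hormone receptors in wild type (camera adjusted p = 0.502) and ribosomal proteins in daf-16 (0.0417) for the food effect. Leaving out 1 library reversed these, with the range over libraries in parentheses: the respiratory chain for the food effect in daf-16 (0.288 without BW25113 replicate 2; 1.99e-07 to 0.54), the genotype effect on BW25113 food (0.031 without BW25113 replicate 2 of daf-16; 1.25e-05 to 0.905) and the interaction (0.00119 without BW25113 replicate 1 of daf-16; to 0.776); ribosomal proteins for the genotype effect on BW25113 food (0.0244 without BW25113 replicate 2 of daf-16; 1.9e-05 to 0.905); sperm genes for the genotype effect on hns food (0.0122 and 0.0276 without hns replicate 1 of wild type or of daf-16; 0.00391 to 0.749); and collagens for the interaction (0.722 without hns replicate 2 of wild type; from 1.75e-09).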

Other observations

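The tests of the single genes in this part were read only after the result was seen, and their genes were chosen after their values were seen. Among genes of sulfur amino acid metabolism, the rise of cth-1 on hns food was not shared by its relatives past the threshold. The second cystathionine gamma-lyase gene cth-2 gave limma log2 fold changes of -0.1 ± 0.09 in wild type and -0.04 ± 0.09 in daf-16 (SE, adjusted p = 0.571 and 0.938). The cystathionine beta-synthase gene cbs-1 gave 0.48 ± 0.13 and 0.31 ± 0.13 (limma adjusted p = 0.173 and 0.776), the cysteine dioxygenase gene cdo-1 gave -0.03 ± 0.13 and -0.07 ± 0.13 (0.927 and 0.921), and the methionine synthase gene metr-1 gave -0.39 ± 0.1 and -0.3 ± 0.1 (0.149 and 0.625). Protease genes moved in both directions on hns food. The aspartic protease gene asp-14 rose 5.13-fold in wild type (33.1 ± 0.387 to 170 ± 1.34 FPKM) and 5.11-fold in daf-16 (28.6 ± 5.07 to 146 ± 8.21 FPKM, SD, n = 2; limma adjusted p = 0.000696 and 0.000645), while asp-10, cpr-4 and cpr-5 fell. Further genes of heme handling fell in both genotypes, hrg-2 by 6.77-fold and 8.22-fold (limma adjusted p = 0.0296 and 0.0207) and the exporter gene mrp-5 by 2.1-fold and 2-fold (limma adjusted p = 0.0055 and 0.0072). The lipid-binding protein gene lbp-3 (1.57-fold and 1.92-fold) and the ammonium transporter gene amt-4 (1.61-fold and 1.59-fold) also fell in both (limma adjusted p = 0.0126 and 0.00187, and 0.0209 and 0.0235).

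Some genes differed with food and with genotype. F35E12.5 stood at 39.9 ± 6.44 FPKM in wild type on BW25113 food, at 106 ± 1.24 and 103 ± 17.8 FPKM with 1 of the changes, and at 276 ± 28.9 FPKM in daf-16 on hns food (SD, n = 2), with an interaction of -0.02 ± 0.22 (SE, limma adjusted p = 1). The near-identical copies pud-3 and pud-4, whose values are uncertain, rose in daf-16 on hns food, pud-3 3.33-fold (248 ± 12 to 825 ± 9.95 FPKM) and pud-4 3.49-fold (138 ± 19.7 to 483 ± 72.3 FPKM, n = 2; limma adjusted p = 0.0165 and 0.0309). In wild type their food changes of 1.12 ± 0.17 and 1.18 ± 0.21 missed the threshold (limma adjusted p = 0.0535 and 0.0658). In daf-16 on BW25113 food pud-3 fell (-1.59 ± 0.17, limma adjusted p = 0.0396) and pud-4 gave -1.66 ± 0.21 (0.0529). C44H4.10 was lowest in wild type on BW25113 food, at 1.34 ± 0.569 FPKM, against 10.6 ± 0.796, 7.73 ± 1.79 and 7.02 ± 0.352 FPKM in wild type on hns food and daf-16 on BW25113 and hns food (n = 2), with an interaction of 2.44 ± 0.31 (limma adjusted p = 0.129). The chromatin protein gene hmg-11 was lowest in the same group, at 113 ± 3.84 FPKM, against 209 ± 24.1, 213 ± 22.7 and 241 ± 10.7 FPKM in the other 3, named as before (interaction 0.69 ± 0.15, limma adjusted p = 0.783). For C44H4.10 and hmg-11 the food effect in wild type and the genotype effect on BW25113 food rest on the same low group. They are therefore not 2 separate responses.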
